A study of Mus musculus with 6 samples.

How the data were processed

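RNA was sequenced from 6 samples of mouse bone marrow-derived macrophages, 3 given medium of normal chondrocytes (C CM) and 3 given medium of apoptotic chondrocytes (AC CM), grouped by the treatment named in each sample's title. Per the labels' protocols, total RNA went through an mRNA library kit and was sequenced on an Illumina instrument. A step that keeps strand is not stated, so reads shared by overlapping genes on opposite strands may not be separable. Such genes were tested with their counts as deposited.

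The submitters deposited a single table with 52550 genes. Its read counts per gene are whole numbers that the authors deposited without normalization, as the differing totals per sample show. The normalized signal columns that the authors deposited equal each sample's counts divided by a constant per sample, as found from the values, and were not used for tests. The deposited log2 fold changes, p-values and adjusted p-values are the authors' own comparison of the same groups and were only read and counted. The adjusted p-values equal a Benjamini-Hochberg adjustment over the 27127 genes with a p. Per the submitters' processing notes, fastp 0.17.1, HISAT2 2.1.0, DESeq2 1.18.1 and R 3.4.3 were used, with no roles given. The counting program, the genome build and the annotation are not given in the sources used here. Coordinates are those of the deposited table: 95.2% of the gene identifiers matched to GENCODE release M21 had the same chromosome, start and end as in that annotation of GRCm38. For 27 genes whose symbols had been turned into dates by a spreadsheet, the symbol was restored from the gene identifier. The 37 mitochondrially encoded genes were at 0 in every library, so the share of mitochondrial reads could not be used to judge the RNA.

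The counts summed to between 65630784 and 80105872 per library. Low counts favoured multiples of 4: between 394 and 446 genes had a count of 3 in a library but 696 to 814 had a count of 4, and between 174 and 212 genes had a count of 7 but 374 to 415 had a count of 8. The counter behind this is not known here, so totals may overstate the number of independent fragments, and an analysis of counts divided by 4 was added after the data were seen.

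Genes were filtered with edgeR's filterByExpr, which left 17863, scaled by TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjustment. Counts scaled to a common library size (CPM) use the TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 between genes and adjustment over the 33 lists, and again with an estimated correlation and with fry. A list's members were also adjusted over the list alone. Where several entries share a symbol, the entry with the most counts was used. DESeq2 1.42.0 and limma-voom were run as alternatives, along with other scalings, other filters on low counts, the replicate number as a block, the 20 most counted genes left out, and each replicate left out in turn. The main test, these alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Lists of hepatocyte genes, genes that escape X inactivation and ERK targets were written after the data were seen. Further alternatives were added after the data were seen: genes on X and Y left out, AC CM replicates 2 and 3 left out, and counts divided by 4. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

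The lists covered pro-inflammatory genes, chemokines, alternative activation, interferon-stimulated genes, MHC class II and class I, the inflammasome, apoptotic cell clearance, cholesterol efflux and synthesis, glycolysis, hypoxia, oxidative phosphorylation, NRF2 targets, the integrated stress response, p53 targets, lysosome, matrix proteolysis, growth factors and matrix, osteoclasts, the G2 and M phases, the S phase, immediate early genes, and sex-linked genes. Marker lists covered macrophages, monocytes, neutrophils, dendritic cells, lymphocytes, mast cells and basophils, erythroid cells and megakaryocytes, chondrocytes and fibroblasts. The genes named are drawn from the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, a symbol that is not a predicted gene and no overlap between the groups; the 5 smallest p-values in each direction; up to 4 members of each list with the smallest p, or, for marker lists, past the threshold; and Il1b, Tnf, Il6, Nos2, Arg1, Mrc1, Il10, Tgfb1, Mertk, Vegfa, Abca1, Spp1, Cd86 and Chil3 in every case. Rbpj, Ndufs5, Adgre1, Cd68, Col2a1, Tsix and the liver genes fall outside that rule and were named after their values were seen. Some genes that the rule takes are not reported here.

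The procedure was tested on counts simulated from the means and library sizes of this comparison, with 200 genes changed and 17413 to 17503 tested, in 10 simulations for each of 2 ways of drawing the spread. With a spread of its own for each gene, the share of false calls averaged 10.7% (8.70% to 12.7%), above the nominal level, and with the spread following the trend with expression it averaged 4.54% (0% to 7.69%). The test recovered 29.6% and 28.9% of genes changed 1.5-fold, 57.5% and 59.5% of those changed 2-fold and 79.8% and 85.3% of those changed 4-fold, for the gene-wise and the trended spread. The simulations changed 200 genes, far fewer than the 4741 called in the data. The shares of false calls and of recovered genes therefore need not hold for those calls. A raised list of 20 genes was called in 10 of 10 simulations with either spread, and an unchanged list in 0 and 1 of 10. Each gene was drawn independently, so these list results do not cover lists whose genes correlate. Every member of the raised list was raised, so lists whose members go both ways are not covered either. With 3 samples against 3, a permutation of the samples cannot reach a p of 0.05, and the 10 splits of the samples are given as counts.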

Results

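Libraries for mRNA sequencing were made from mouse macrophages grown out of C57BL/6 bone marrow with macrophage colony-stimulating factor (M-CSF, 25 ng/ml, 7 days). The cells were then exposed to culture medium of normal chondrocytes (C CM, 3 samples) or of apoptotic chondrocytes (AC CM, 3 samples). Gene counts summed to 65630784, 68852308 and 65996152 in C CM replicates 1, 2 and 3, and to 70802852, 77377073 and 80105872 in AC CM replicates 1, 2 and 3. The labels do not say whether the 3 samples of a group came from separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical. Replicates of a group were not copies of each other, with a chi-square per gene between 27.1 and 62.7 for the pairs. Values after ± are SD over n = 3 samples, and log2 fold changes are AC CM over C CM with their standard error (SE).

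The series has a single contrast, which asks how medium of apoptotic chondrocytes changes macrophage expression. Ccl7, a chemokine that attracts monocytes, was 14.5-fold higher after AC CM (120 ± 1.77 against 8.26 ± 0.629 CPM, counts scaled to library size). Its neighbour Ccl2 was 7.64-fold higher (87.6 ± 7.65 against 11.5 ± 1.41 CPM). Plau, which encodes urokinase, rose 6.10-fold to 461 ± 11.5 CPM. The cell cycle gene Ccnd1 rose 6.02-fold to 644 ± 7.92 CPM and the transcription factor gene Etv5 6.54-fold to 195 ± 2.08 CPM. MHC class II genes moved the other way. H2-Aa, an MHC class II chain, fell from 84.4 ± 1.86 to 6.12 ± 0.982 CPM, and the invariant chain gene Cd74 fell 13.5-fold from 311 ± 45.2 CPM. Ciita, the transactivator of the class II genes, fell from 11.5 ± 0.998 to 0.448 ± 0.234 CPM.

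Among the genes that rose most, Ccl7 (ENSMUSG00000035373.2, chromosome 11, 82045712 to 82047525, plus strand) had a log2 fold change of 3.86 (SE 0.09, adjusted p = 1.34e-07). Ccl2 (chromosome 11, 82035571 to 82037453) rose by 2.93 (SE 0.12, adjusted p = 1.04e-06). Etv5 (chromosome 16, 22381309 to 22439719) rose by 2.71 (SE 0.08, adjusted p = 3.4e-07) and Plau (chromosome 14, 20836660 to 20843385) by 2.61 (SE 0.09, adjusted p = 3.9e-07). The calcium channel gene Cacna1a rose by 3.45 and Gdpd3 by 2.82. Ccnd1 (chromosome 7, 144929931 to 144939925, minus strand) rose by 2.59 (SE 0.08, adjusted p = 3.4e-07). Oraov1 rose by 2.26, but it lies at 144915100 to 144931701 on the plus strand and overlaps Ccnd1. Whether the counting used strand is not stated, so reads from the stretch that the pair shares may not be separable. The processed pseudogene Rbpsuh-rs3 rose by 3.59 while its parent Rbpj fell by 0.61 on the log2 scale. The pseudogene BC002163 rose by 4.53 while its parent Ndufs5 fell by 1.03. Both values are uncertain because a pseudogene can take reads of its parent. Among the genes that fell most, Cyp4f18 (ENSMUSG00000003484.4, chromosome 8, 71988482 to 72009626), a cytochrome P450, changed by -5.47 (SE 0.18, adjusted p = 3.9e-07) and Ciita (chromosome 16, 10488178 to 10527564) by -4.69 (SE 0.32, adjusted p = 2.44e-05; -4.02 with AC CM replicates 2 and 3 left out). Mamdc2 changed by -3.94, H2-Aa (chromosome 17, 34282744 to 34287827) by -3.78 (SE 0.12, adjusted p = 3.9e-07) and Cd74 by -3.75. Hpgd, which degrades prostaglandins, changed by -3.10 and the immunoglobulin heavy chain gene Ighm by -2.84. Adgre4 changed by -2.62, the granule protein gene Ngp by -2.57 and Lpcat2 by -2.28.

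**Figure D1:**
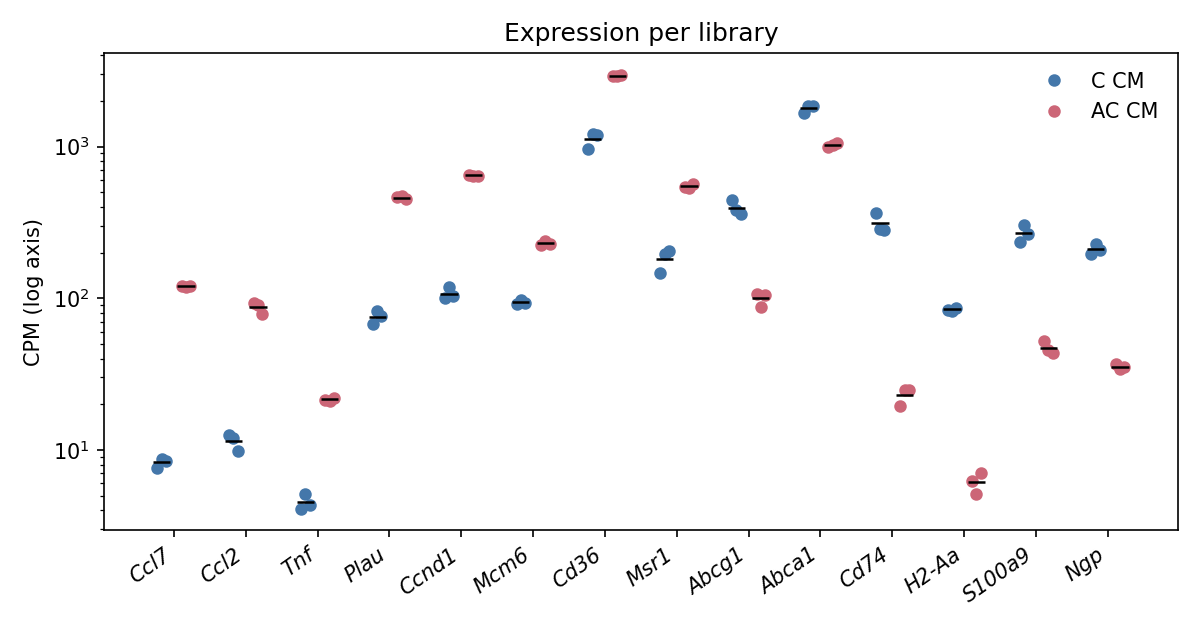
CPM on a log axis for 14 genes in each library, with 1 point per library and a black bar at the group mean of the 3 samples. The groups do not overlap for any of the genes drawn, with Ccl7 at 120 CPM after AC CM against 8.26 CPM after C CM and H2-Aa at 6.12 against 84.4 CPM.

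Of 17863 genes tested with edgeR's quasi-likelihood test, 4741 differed at a Benjamini-Hochberg adjusted p under 0.05, 2370 higher and 2371 lower after AC CM. Of these, 1115 also differed at least 2-fold, 375 higher and 740 lower, a size filter and not a test against 2-fold. The first principal component held 50.9% of the variance and separated the groups. Libraries correlated at 0.974 to 0.980 within a group and at 0.946 to 0.960 between groups. Without AC CM replicate 3 the count of changed genes was 3158. With AC CM replicates 2 and 3 left out, the libraries with the most hepatocyte transcripts, it was 1274, in a fit that assumes the remaining AC CM library varies like the C CM libraries. The authors' deposited table called 5060 genes at an adjusted p under 0.05, 2636 higher and 2424 lower. Of these, 4617 were also called here, all 4617 in the same direction. Of the 17863 genes tested in both, a further 124 were called here only and 295 in the authors' deposited table only. The other 148 genes called in the deposited table were filtered out here for low counts.

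Gene lists fixed before the data were examined were each described by their members and tested as a set with limma's camera. With a preset correlation between genes, 14 of 33 lists passed at an adjusted p under 0.05. With an estimated correlation 0 passed, and the smallest adjusted p was 0.0641. At an unadjusted p under 0.05 there were 6 lists with the estimated correlation and 16 with the preset. By limma's fry, which asks whether a list's own genes move one way on balance, 26 passed. Counts of members that rose or fell are those at an adjusted p under 0.05 over all genes tested.

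Of 22 chemokine genes tested, 9 rose, 5 fell and 8 did not pass. Ccl12 rose by 2.07 (SE 0.11) and Ccl4 by 1.43 (SE 0.10), next to Ccl7 and Ccl2. As a set the list did not pass (camera adjusted p = 0.128). Of 17 pro-inflammatory genes, 4 rose, 7 fell and 6 did not pass. The set did not pass either (camera adjusted p = 0.253). Tnf rose by 2.26 (SE 0.12, adjusted p = 7.01e-06) from 4.51 ± 0.538 to 21.5 ± 0.516 CPM and the costimulatory ligand gene Tnfsf9 by 2.56 (SE 0.19). The costimulatory genes Cd86 and Cd40 changed by -1.04 and -0.94. The nitric oxide synthase gene Nos2 changed by -1.60 (adjusted p = 0.0127) and Il1b by -0.77 (adjusted p = 0.0326). The Il1b call was lost without C CM replicate 2 (adjusted p = 0.0916), C CM replicate 3 (0.102), AC CM replicate 2 (0.101) or AC CM replicate 3 (0.0779). Il6 was too low to be tested. Of 14 inflammasome genes 1 rose, 5 fell and 8 did not pass (camera adjusted p = 0.140). Mefv, the pyrin gene, was at -1.35 and the ATP receptor gene P2rx7 at -0.97. Of 30 interferon-stimulated genes 1 rose, 11 fell and 18 did not pass. Gbp2 was at -1.21, Gbp3 at -1.03 and Ifit2 at -0.83, and the single rise was in Xaf1, at 1.11. That list was lower as a set (camera adjusted p = 0.00276), but not with an estimated correlation (adjusted p = 0.410). Adjusted over the list alone, 10 chemokines rose and 5 fell. The counts of the pro-inflammatory, inflammasome and interferon lists were the same.

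Of 18 genes of alternative activation, 3 rose, 7 fell and 8 did not pass, with the same counts adjusted over the list alone. Chil3, a chitinase-like protein gene, fell by 2.20 on the log2 scale from 167 ± 22.2 to 36.4 ± 2.59 CPM. Ear2 changed by -2.55, the transcription factor gene Irf4 by -1.31 and the lectin gene Clec10a by -0.98. The mannose receptor gene Mrc1 rose by 0.54 (SE 0.10). Il10 was at 0.27 (SE 0.13, adjusted p = 0.167) and Tgfb1 at -0.02 (SE 0.11, adjusted p = 0.907). The list was lower as a set (camera adjusted p = 0.0222), but not with an estimated correlation (adjusted p = 0.265) or without C CM replicate 1 (adjusted p = 0.0907). Arg1, the arginase gene, rose by 3.14 (SE 0.77, adjusted p = 0.0296) from 0.577 ± 0.364 to 5.08 ± 3.43 CPM, with a wide spread between the AC CM libraries. Its call was lost without C CM replicate 1 (log2 fold change 3.75, adjusted p = 0.0547), C CM replicate 2 (0.0797), C CM replicate 3 (0.110) or AC CM replicate 2 (0.0731). With AC CM replicates 2 and 3 left out it was at 1.36 (adjusted p = 0.297). Arg1 is also abundant in hepatocytes, and its counts were highest in the same libraries as those of hepatocyte genes.

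All 10 MHC class II genes tested fell, also when adjusted over the list alone. H2-Eb1 was at -3.61 (SE 0.15) and H2-Ab1 at -3.56 (SE 0.18), beside H2-Aa, Cd74 and Ciita. The list was lower as a set (camera adjusted p = 1.06e-09), with an adjusted p = 0.0641 with an estimated correlation. Of 14 MHC class I genes 4 rose, 3 fell and 7 did not pass, with the same counts adjusted over the list alone, and the set did not pass (camera adjusted p = 0.706). H2-Q7 was at 0.59, the transactivator gene Nlrc5 at -0.37 and Tapbp at -0.53.

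Markers of other bone marrow cells fell alongside the MHC class II genes. Of 13 neutrophil and granulocyte precursor genes 12 fell and 1 did not pass. Beside Ngp, S100a9 was at -2.51 (267 ± 34.6 to 46.9 ± 4.46 CPM), the lactoferrin gene Ltf at -2.16 and the myeloperoxidase gene Mpo at -1.50. The list was lower as a set (camera adjusted p = 2.33e-12), with an adjusted p = 0.0641 with an estimated correlation. Of 12 monocyte genes 8 fell and 4 did not pass. Ccr2, the receptor for Ccl2 and Ccl7, was at -1.62, F13a1 at -1.66 and Plac8 at -0.86. Cd177, on this list but better known as a neutrophil gene, was at -2.34. As a set the monocyte genes were lower (camera adjusted p = 1.78e-06), with an adjusted p = 0.0890 with an estimated correlation. Of 14 B, T and NK cell genes 12 fell and 2 did not pass. Cd79a was at -3.81 (SE 0.54), Nkg7 at -2.30 and Cd4 at -1.05. After C CM, Cd4 (111 ± 7.75 CPM) was more abundant than Cd79a (2.21 ± 0.418), Nkg7 (2.34 ± 0.245) or Cd79b (20.5 ± 2.57). The fall of Cd4 need not be that of lymphocytes. Cd79a had 19, 3 and 13 counts in AC CM replicates 1, 2 and 3, and was at -4.43 without AC CM replicate 1 and at -3.03 with AC CM replicates 2 and 3 left out. These too were lower as a set (camera adjusted p = 3.79e-06), with an adjusted p = 0.0890 with an estimated correlation. Of 13 dendritic cell genes 9 fell, 1 rose and 3 did not pass. The chemokine receptor gene Ccr7 was at -4.58 (SE 0.47), Dpp4 at -2.24 and Itgax at -1.94, against Bst1 at 0.83. Ccr7 had 12, 4 and 4 counts in AC CM replicates 1, 2 and 3, and was at -5.37 without AC CM replicate 1 and at -3.66 with AC CM replicates 2 and 3 left out. The dendritic cell list was lower as a set (camera adjusted p = 1.75e-04), with an adjusted p = 0.0890 with an estimated correlation. Of 5 mast cell and basophil genes Kit (-2.14) and Prss34 (-1.81) fell and 3 did not pass. The set did not pass (camera adjusted p = 0.0715), but did without C CM replicate 1 (0.0490) or AC CM replicate 1 (0.0264). Of 10 erythroid and megakaryocyte genes the platelet genes Itga2b (-2.39) and Gp9 (-2.36) fell and 8 did not pass (camera adjusted p = 0.202). Adjusted over the list alone, 10 monocyte genes fell and 1 rose, and 11 dendritic cell genes fell and 1 rose. The counts of the granulocyte, lymphocyte, mast cell and erythroid lists were the same. Of 12 macrophage genes 4 fell and 8 did not pass, also over the list alone. The M-CSF receptor gene Csf1r was at -0.72 (3317 ± 89.9 to 2021 ± 84.0 CPM) and Mertk at -0.40. The call for Cd14 (-0.30) was lost without C CM replicate 2 (adjusted p = 0.0577) or AC CM replicate 1, 2 or 3 (adjusted p = 0.0539 to 0.102). Adgre1, which encodes F4/80, was at -0.19 (adjusted p = 0.0974) and Cd68 at 0.15 (adjusted p = 0.138). The macrophage list was lower as a set (camera adjusted p = 0.0459), but not with an estimated correlation (adjusted p = 0.270) or without C CM replicate 2 (adjusted p = 0.0801). The macrophage call was also lost with AC CM replicates 2 and 3 left out (adjusted p = 0.0574) and with counts divided by 4 (adjusted p = 0.0559).

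**Figure D2:**
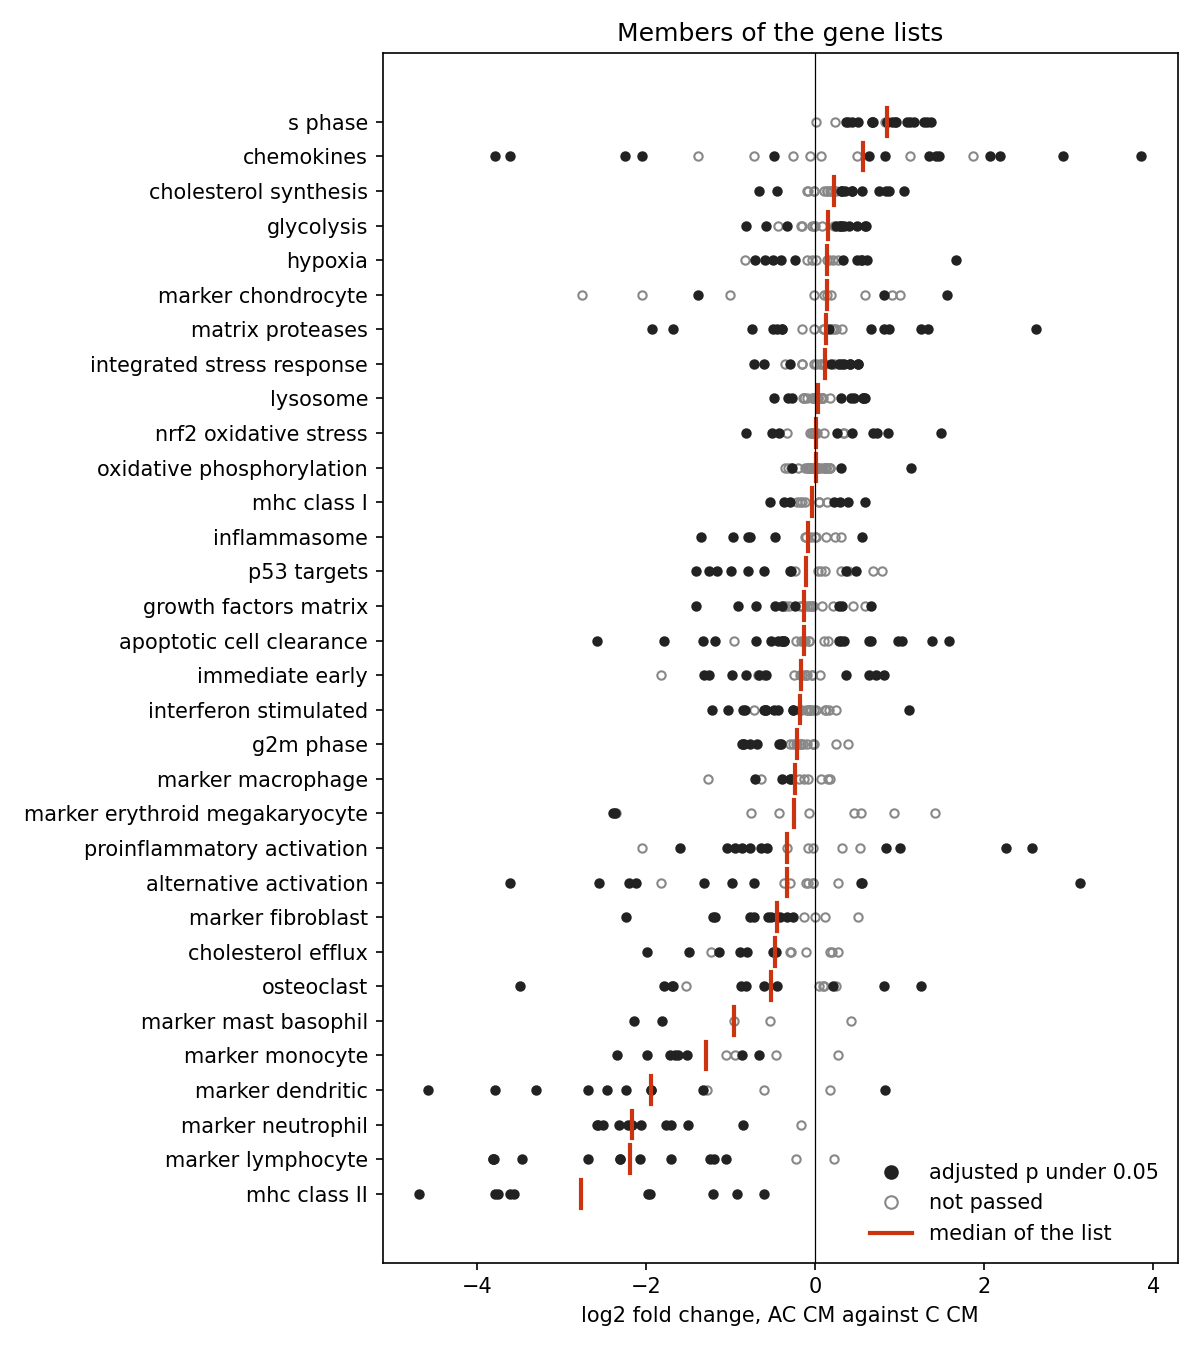
Log2 fold change, AC CM over C CM, of each tested member of 32 gene lists (the sex-linked list is not drawn), filled where the adjusted p over all genes was under 0.05 and open where not, with a red bar at each list's median. The MHC class II, lymphocyte, neutrophil and dendritic cell lists have the lowest medians (-2.77, -2.19, -2.16 and -1.95) and the S phase list the highest (0.85).

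Of 30 genes of apoptotic cell clearance 9 rose, 11 fell and 10 did not pass, and the set did not pass (camera adjusted p = 0.329). The scavenger receptor genes Cd36 and Msr1 rose by 1.39 (1122 ± 135 to 2936 ± 33.8 CPM) and 1.58 (182 ± 31.8 to 546 ± 18.2 CPM), and the lipid receptor gene Cd300lf by 0.98. The integrin gene Itgb3 changed by -1.78 and the receptor gene Mertk by -0.40 (SE 0.07). Of 14 genes of cholesterol efflux and LXR targets 7 fell, 0 rose and 7 did not pass. The lipid exporter genes Abcg1 and Abca1 were at -1.99 (395 ± 45.0 to 99.6 ± 10.7 CPM) and -0.81 (1795 ± 107 to 1024 ± 30.1 CPM), and the phospholipid transfer gene Pltp at -1.49. That list was lower as a set (camera adjusted p = 1.26e-04), but not with an estimated correlation (adjusted p = 0.265). Of 24 genes of cholesterol synthesis 10 rose, 2 fell and 12 did not pass, with the enzyme genes Sqle at 0.84 and Msmo1 at 1.06. This list was higher as a set (camera adjusted p = 0.00704), but not with an estimated correlation (adjusted p = 0.408) or with AC CM replicates 2 and 3 left out (adjusted p = 0.120). Of 26 lysosomal genes 7 rose, 3 fell and 16 did not pass, with Ctsl at 0.60, Gla at 0.57 and Psap at -0.48. That set did not pass (camera adjusted p = 0.176). Adjusted over the list alone, 9 clearance genes rose and 12 fell, and 1 efflux gene rose and 9 fell. By the same adjustment, 11 synthesis genes rose and 2 fell, and 8 lysosomal genes rose and 3 fell.

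Of 21 S phase and replication genes 18 rose, 0 fell and 3 did not pass. The replicative helicase genes Mcm2 and Mcm6 rose by 1.38 (SE 0.07) and 1.29 (SE 0.06), Mcm6 from 94.0 ± 3.26 to 230 ± 7.49 CPM. The list was higher as a set (camera adjusted p = 2.33e-12), with an adjusted p = 0.131 with an estimated correlation. Of 22 G2 and M phase genes 7 fell, 0 rose and 15 did not pass, with the mitotic regulators Cdc20 at -0.85, Plk1 at -0.84 and Ccnb2 at -0.87. That list was lower as a set (camera adjusted p = 0.00681), but not with an estimated correlation (adjusted p = 0.464), by fry (adjusted p = 0.0633) or without C CM replicate 2 (adjusted p = 0.0945). Of 18 p53 targets 2 rose, 8 fell and 8 did not pass, with Gdf15 at -1.41 and Btg2 at -1.25 (camera adjusted p = 0.140). Of 22 immediate early genes 4 rose, 6 fell and 12 did not pass, with Fos at 0.81, Btg2 at -1.25 and Hspa1b at -0.98. The set did not pass (camera adjusted p = 0.102), but did without C CM replicate 3 (0.0382). Adjusted over the list alone, 19 S phase genes rose, 4 immediate early genes rose and 8 fell, and the G2 and M phase and p53 counts were the same.

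Of 20 glycolytic genes 9 rose, 3 fell and 8 did not pass, with Gapdh at 0.59, Pgk1 at 0.50 and Pfkp at 0.61. The set did not pass (camera adjusted p = 0.0790), but did without C CM replicate 1 (0.0168). Of 19 hypoxia genes 6 rose, 5 fell and 8 did not pass (camera adjusted p = 0.434), with P4ha1 at 0.62 and Mxi1 at -0.71. Vegfa was at -0.24 (SE 0.07, adjusted p = 0.0392). Its call was lost without C CM replicate 2 (adjusted p = 0.0590), C CM replicate 3 (0.0601) or AC CM replicate 1 (0.0968), 2 (0.154) or 3 (0.0878). Of 30 oxidative phosphorylation genes Cycs (1.13) and Atp5b (0.31) rose, Cox4i1 was called at -0.28 and 27 did not pass (camera adjusted p = 0.560). The Cox4i1 call was lost without C CM replicate 2 (adjusted p = 0.0788) and without AC CM replicates 1 (0.0976), 2 (0.146) or 3 (0.146). Of 20 NRF2 targets 6 rose, 3 fell and 11 did not pass (camera adjusted p = 0.302). The cystine transporter gene Slc7a11 was at 1.49, the thioredoxin reductase gene Txnrd1 at 0.73 and the catalase gene Cat at -0.82. Of 21 genes of the integrated stress response 8 rose, 3 fell and 10 did not pass, with Atf4 at 0.41 and Herpud1 at -0.72. That set did not pass (camera adjusted p = 0.140), but did without C CM replicate 1 (0.0426). Adjusted over the list alone, 10 glycolytic genes rose and 3 fell, and 2 oxidative phosphorylation genes rose and 0 fell. By the same adjustment, 7 NRF2 targets rose and 3 fell, 9 stress response genes rose and 3 fell, and the hypoxia counts were the same.

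Of 22 genes of matrix proteolysis 7 rose, 7 fell and 8 did not pass (camera adjusted p = 0.369). Next to Plau, the metalloprotease gene Adam8 rose by 1.33 (734 ± 73.4 to 1845 ± 17.1 CPM), while Mmp12 changed by -1.92 (226 ± 45.8 to 59.7 ± 6.91 CPM) and Mmp9 by -1.68. Of 16 osteoclast genes 3 rose, 8 fell and 5 did not pass (camera adjusted p = 0.128). The RANK receptor gene Tnfrsf11a rose by 1.25 (96.2 ± 2.91 to 230 ± 2.58 CPM) and the fusion gene Dcstamp changed by -3.49 (SE 0.43; -4.16 with AC CM replicates 2 and 3 left out). Of 24 growth factor and matrix genes 3 rose, 6 fell and 15 did not pass (camera adjusted p = 0.140), with Lgals3 at 0.67 and Pdgfb at -0.91. Spp1, the osteopontin gene, was at 0.31 (SE 0.08, adjusted p = 0.0150), a call lost without AC CM replicate 1 (adjusted p = 0.0522) or replicate 3 (0.0674). Of 15 fibroblast genes 11 fell, 0 rose and 4 did not pass, with Col6a1 at -1.18 (282 ± 15.7 to 125 ± 3.42 CPM), Col6a2 at -1.20 and Pdgfrb at -0.56. The fibroblast list was lower as a set (camera adjusted p = 3.3e-05), but not with an estimated correlation (adjusted p = 0.270). Of 13 chondrocyte genes, markers of the cells that made the medium, Col11a1 (0.81) and Prg4 (1.56) rose, Col9a3 was called at -1.38 and 10 did not pass. Col2a1, among the latter, was at 0.19 (adjusted p = 0.179). The Prg4 call was lost without C CM replicate 3 (adjusted p = 0.0538) or AC CM replicate 2 (0.0774), and the Col9a3 call was lost with each of the 6 replicates left out in turn (adjusted p of at least 0.0590). The list's median (0.14) and test pointed up where its mean (-0.15) was negative (camera adjusted p = 0.549). Adjusted over the list alone, 9 proteolysis genes rose and 7 fell, and 4 osteoclast genes rose and 8 fell. By the same adjustment, 4 growth factor genes rose and 7 fell, 1 fibroblast gene rose and 11 fell, and 2 chondrocyte genes rose and 2 fell.

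Sex-linked and hepatocyte transcripts also differed between the libraries. Xist, the transcript of the inactive X chromosome, had 37, 97 and 263 counts in C CM replicates 1, 2 and 3 and 94933, 111486 and 118589 counts in AC CM replicates 1, 2 and 3 (log2 fold change 9.50, SE 0.81, adjusted p = 0.00224). Without C CM replicate 3 the log2 fold change was 10.48. The Xist locus overlaps the antisense gene Tsix, and whether the counting used strand is not stated. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were present in all 6 libraries and fell after AC CM, at -1.04, -1.60, -1.09 and -1.36. Of the 5 sex-linked genes 1 rose and 4 fell, also over the list alone. The list's mean was 0.88, its median -1.09 and its test lower (camera adjusted p = 0.0247; adjusted p = 0.410 with an estimated correlation). The labels give no sex, and the sex-linked transcripts and the medium differed between the same samples. Albumin (Alb) had 1972, 90 and 17 counts in C CM replicates 1, 2 and 3 and 2684, 36283 and 77432 counts in AC CM replicates 1, 2 and 3. Arg1 was highest in AC CM replicates 2 and 3 as well. The liver enzyme gene Hpd had 0 counts in every C CM library and 73, 171 and 168 in AC CM replicates 1, 2 and 3. Leaving out the genes on X and Y gave 4612 changed genes.

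**Figure D3:**
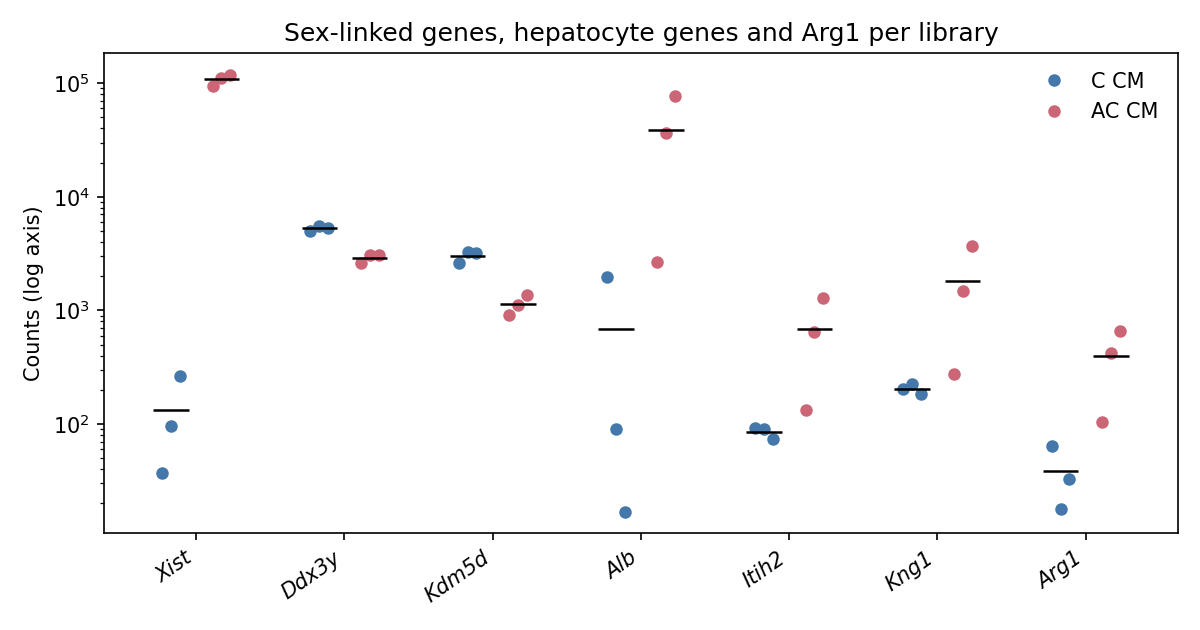
Counts on a log axis of 7 genes in each library, with 1 point per library and a black bar at the group mean of the 3 samples. Xist lies at 37 to 263 counts in the C CM libraries and at 94933 to 118589 in the AC CM libraries, whereas Alb, Itih2, Kng1 and Arg1 are highest in AC CM replicates 2 and 3, Alb with 36283 and 77432 counts.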

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

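The alternatives that leave out the genes on X and Y, leave out AC CM replicates 2 and 3, or divide the counts by 4 were chosen after the data were seen. The count of changed genes, 4741, stayed within 1.5 times that value with other size factors (4727), upper quartile scaling (4692), no filter (4389), a stricter filter (4037), DESeq2 (5370), limma-voom (4822), the most counted genes left out (4723), X and Y left out (4612) and counts divided by 4 (4849). Leaving out each replicate in turn gave 3158 to 5023 genes, the lowest without AC CM replicate 3, and leaving out AC CM replicates 2 and 3 gave 1274, where 1 AC CM sample remains and is assumed to vary like the others. The count of genes changed at least 2-fold, 1115, was 426 with the stricter filter, which tests fewer low genes, 989 to 1187 with each replicate left out, 751 with AC CM replicates 2 and 3 left out, 1352 with DESeq2, 995 with counts divided by 4, and 1082 to 1174 in the other fits without a block. The count of lists past the threshold, 14, was 0 with an estimated correlation and 26 with fry, and 12 to 16 with each replicate left out. It was 14 with the other size factors. It was also 14 with AC CM replicates 2 and 3 left out, where cholesterol synthesis (adjusted p = 0.120) and macrophage markers (0.0574) were lost and immediate early genes (0.0436) and erythroid and megakaryocyte markers (0.0416) gained. It was 14 again with counts divided by 4, where macrophage markers (0.0559) were lost and mast cell and basophil markers (0.0322) gained. Fry tests another question. The cause of the lists lost with an estimated correlation was not tested. For MHC class II (-0.0142) and dendritic cell markers (-0.0508) the estimate lay below the preset 0.01, so a higher correlation does not account for their loss. For the other lists lost the estimate lay above 0.01. Of 152 named genes tested, 144 were called, 0 of 152 reversed in any fit, 10 lost their call with some replicate left out, 6 in another planned fit, 40 with AC CM replicates 2 and 3 left out, and 3 gained a call in a planned fit. Arg1 was lost with no filter (adjusted p = 0.0550) and limma-voom (adjusted p = 0.133), over a range of its alternatives up to 0.297. The alternatives for normalized values did not apply, since counts were given. Low counts favour multiples of 4, which limits the precision of folds of genes near the filter.

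With the replicate number as a block, 4397 genes, 1024 genes at least 2-fold and 14 lists passed. The numbers do not pair the samples: deviations from the group means correlated at -0.116, -0.0306 and -0.0135 for the same-numbered samples 1, 2 and 3, and 0 of the 6 samples correlated best with its own number. Under the block, Arg1 (adjusted p = 0.155), Col9a3 (0.0945), Il1b (0.0538) and Vegfa (0.0544) were not called.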

Other observations

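The tests of sex makeup, macrophage markers, a shared hepatocyte response, Arg1, granulocytes and MHC class II against other cells were chosen after the results they weigh had been seen. The tests of unseen hepatocyte genes, GC content and length, unseen ERK targets and splits of the samples were written before their results were seen. The readings of the MHC class II, ERK, granulocyte and Arg1 tests were made more cautious after their values were seen. The genes in the paragraph that follows were picked after their values were seen, and none of these groupings was tested for enrichment.

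Several complement genes rose after AC CM. C4b rose by 1.70 (SE 0.11), C2 by 1.36 (SE 0.10), Cfb by 1.02 (SE 0.07), the anaphylatoxin receptor gene C5ar1 by 1.38 (SE 0.08) and C3ar1 by 0.46 (SE 0.07), while Cd55, which restrains complement, changed by -1.62 (SE 0.19). C1qa was at -0.07 (adjusted p = 0.649) and C3 at -1.14 with a wide SE of 0.40 (adjusted p = 0.109). The chemokine receptor genes went separate ways, with Ccr1 at 1.52 against Ccr2 at -1.62 and Cxcr4 at -1.58.

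Among the genes seen to rise, 7 are known as targets or feedback regulators of the ERK pathway: Etv5 (2.71), Etv1 (2.53), Ccnd1 (2.59), Dusp4 (2.44), Spred2 (2.02), Spry2 (1.69) and Spred1 (1.52). They were put together because they rose, so their rise together is no test of the pathway. The hypothesis that ERK targets rose more widely was tested on 8 further targets whose values had not been looked at, and it was not borne out: camera gave an unadjusted p = 0.735, 2 rose (Dusp6 at 1.35 and Epha4 at 0.88), 2 fell (Spry4 at -0.81 and Dusp5 at -0.55) and 4 did not pass. Their median was -0.16 with an SD of 0.73 and their mean 0.02, so members going both ways decide nothing about the pathway itself.

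Xist rose and 4 Y-linked genes fell after AC CM. RNA of female cells other than macrophages, carried over with the medium, would lower macrophage markers as much as the Y-linked genes, but the macrophage median (-0.24) lay 0.987 above the Y-linked median (-1.22), against an SD of 0.259 among the Y-linked genes, so this does not account for the whole fall. A mixture of male and female macrophages in the AC CM cultures is a candidate explanation: the 5 genes that escape X inactivation averaged 0.32, at the 86.06th percentile of 10000 random sets of 5 X-linked genes (median -0.01), with Eif2s3x at 0.71 and Kdm6a at 0.50 called and 3 not. The bound set for the explanation was a percentile of the random sets, not a rise worked out for a mixture. A percentile between that bound and the median of the sets therefore decides neither way. The mean did lie above that median, the side a mixture would give. Camera with the preset correlation gave the same 5 genes higher than all other genes tested (unadjusted p = 0.0401). That list was written after the data were seen, so this p weighs no explanation. A change of Xist alone by the medium would leave the Y-linked genes where they were. All 4 fell without overlap between the groups (median -1.22, SD 0.259), which argues against a change of Xist alone. A change of both Xist and the Y-linked genes by the medium was not tested. Sex makeup and medium cannot be told apart in this design, so any of the changes reported may carry a part due to sex.

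Hepatocyte transcripts were abundant in AC CM replicates 2 and 3. With their spread between AC CM libraries, 5 of 34 tested members of the hepatocyte list rose and 29 did not pass. All 34 had a positive fold. Camera with the preset correlation gave them higher as a set (unadjusted p = 7.54e-05, and 0.00629 for the 16 tested among those not looked at before). The list was written after the data were seen, and a preset correlation of 0.01 allows little for genes that vary together between libraries. These p-values therefore weigh no explanation. Of 18 hepatocyte genes not looked at before, 100% had at least 10 counts in both libraries and exceeded every C CM library, as hepatocyte RNA would give; Fgg, for one, had 37, 0 and 0 counts in C CM replicates 1, 2 and 3 and 145, 1040 and 2669 in AC CM replicates 1, 2 and 3. Kng1, Itih2 and Serpinc1 had 74 or more counts in every library, so the cultured cells may express part of the list. A response shared by the AC CM cultures would raise each gene in all 3 of them, and 52.6% of 38 genes were higher in all 3 than in every C CM library, which decides neither way. The Arg1 ratio of AC CM replicate 3 to replicate 1 was 2.47 on the log2 scale, at the 98.4th percentile of 1443 genes of similar expression, but this restates the library pattern that prompted the test, so reads from hepatocyte RNA and a macrophage response of Arg1 that differs between cultures both stay open.

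Granulocyte markers and MHC class II genes were lower after AC CM. A trend with GC content or length does not account for this: the median of the 23 genes was -2.16 before and -2.09 after the trend was removed, with all 23 genes carrying a value. That 92.3% of the granulocyte markers fell (12 of 13) is the pattern itself and favours neither fewer residual granulocytes in the AC CM cultures nor a response of the macrophages to the medium, and both stay open. For MHC class II, fewer residual B and dendritic cells would lower the chains no more than the markers of those cells; the chains fell further (median -3.68 against -2.07, a gap of 1.61 beyond the markers' SD of 1.40), but 5 of the 27 B, T, NK and dendritic cell markers fell at least as far as the chain that fell least. Those 5 keep residual cells open, so residual cells and a macrophage response cannot be told apart for the class II genes.

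The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4741 genes, 1115 of them at least 2-fold, and 14 lists, and the highest of the other splits called 1 gene, 1 gene at least 2-fold and 10 lists; for each of the 3 counts, 1 of the 10 splits gave a result as large, the real one. Splits that mix the groups called 4 to 10 lists with the preset correlation. Each of them has both media on either side, so the difference between the media adds to the spread. Their few gene calls therefore follow from the design.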
